A study of Mus musculus with 2 samples.

How the data were processed

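Small RNA of the hippocampus was sequenced on an Illumina instrument, with 1 library from a Mecp2-/Y male mouse and 1 library from a wild type male mouse, both at postnatal day 30. The deposited table lists 941 mature miRNAs by name, with 1 column per library, and was matched to the genotypes through the sample titles. Reads were aligned with BWA to the mouse assembly mm9, per the submitters' processing notes. The aligner settings, the rule that assigned reads to mature miRNAs and the miRBase release were not given in the sources used here.

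The deposited values are read counts that were not scaled to library size, and they were read here in the unit of expected counts, since 31 miRNAs hold a value ending in 0.5. All other values are whole numbers. Many of those 31 names belong to miRNAs with several genomic copies, so reads may have been averaged over copies, which the sources used here do not state. Values were rounded to whole numbers, with a remainder of 0.5 rounded up, before any step that needs counts. The rounded totals were 9482368 reads in the wild type library and 10325080 reads in the Mecp2-/Y library. Of the 941 miRNAs, 30 were at 0 in both libraries, 82 were at 0 in the wild type library alone and 50 were at 0 in the Mecp2-/Y library alone. A count of 0 allows up to 3 counts, or 0.350 CPM in the wild type library and 0.262 CPM in the Mecp2-/Y library on the scaled library sizes, where CPM is the count scaled to a common library total.

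Libraries were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, which gave factors of 0.903 for the wild type library and 1.11 for the Mecp2-/Y library. Mean abundance was computed as CPM on these scaled library sizes. A miRNA counted as measured with at least 20 reads over both libraries, which 592 miRNAs reached. The log2 ratio of the Mecp2-/Y to the wild type library was computed without a pseudocount, except that a count of 0 was replaced by 3 counts. Its 95% counting interval came from the exact Clopper-Pearson binomial interval of the Mecp2-/Y share of the miRNA's reads, converted with the scaled library sizes. A measured miRNA was called higher at a ratio of at least 2, or lower at a ratio of at most 1/2, where the interval also excluded 1.

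With 1 library per genotype there is no spread between replicates, so edgeR's quasi-likelihood test could not be fitted and no p-value was computed. The intervals compare these 2 libraries, not the genotypes. Reads copied by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Messenger RNA of Mecp2 was not measured by this assay, so the genotype labels were not checked by the data. Leaving out a replicate was not possible with 1 library per genotype.

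Lists of miRNAs were fixed before the data were examined, as were the calling rule, the rule for named miRNAs and most of the alternatives. An entry of a list took every arm and every genomic copy of that name. The 21 lists with at least 3 measured miRNAs covered the imprinted Dlk1-Dio3 domain in 2 lists (the miR-379 to miR-410 cluster and other miRNAs of the domain, without miR-3070a, miR-3070b, miR-3071, miR-3544 and miR-666, which lie among their hairpins), the cluster of miR-183, miR-96 and miR-182, activity-regulated and neuron-enriched miRNAs, oligodendrocyte, astrocyte, microglia and myeloid, erythroid, endothelial and mural, choroid plexus and ependyma, hindbrain and spinal cord and muscle miRNAs, the let-7, miR-17, miR-29, miR-30 and miR-34 with miR-449 families, Drosha-independent miRNAs, X-linked miRNAs and miRNAs linked to MeCP2 by earlier work. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the measured miRNAs within 10 bins of mean expression. A percentile below 2.5 or above 97.5 was taken as outside the central 95%, where about 1 of 21 lists falls by chance. Random lists break up arms and clusters that share a transcript, so the percentile describes these libraries and is not a test.

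The rule for named miRNAs took the 10 higher and the 10 lower calls whose interval bound nearest to 1 lay farthest from 1, the 5 most abundant miRNAs of the wild type library, every measured arm of miR-134, miR-382, miR-182, miR-383, miR-132, miR-212, miR-137, miR-199a, miR-184, miR-124 and miR-9, and up to 4 of the most abundant members of each list. It named 96 miRNAs. Any other miRNA named in the text was chosen after its values were seen, as were the groups of neighbouring hairpins, host genes and the miR-129 arms. Hairpin neighbours and host genes were taken from RefSeq for GRCm38.p6, which differs from the assembly the reads were aligned to, so names were used and no coordinates. Of the 592 measured miRNAs, 571 were matched to a hairpin of that annotation and 21 were not.

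The ratios of the 5p and 3p arm of a hairpin were correlated across 172 hairpins with both arms measured under the same name, which are not independent replicates. Hairpins with an arm shared between genomic copies beside copy-specific arms, such as those of miR-129, were left out because their arms carry different names. Alternatives were DESeq2 1.42.0 size factors, scaling by the total count, scaling by the total count without the 5 most abundant miRNAs, a minimum of 100 reads, fold thresholds of 1.5 and 3, intervals widened by an assumed coefficient of variation of 20%, and counts summed over arms and copies. Other calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.

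The calling steps were tested on counts simulated for the wild type against Mecp2-/Y comparison, in which 576 miRNAs reached the minimum and 200 miRNAs had been given a known change. The calls recovered 97.9% of the 3-fold changes and 100% of the 6-fold changes in the right direction, and called 0.52% of unchanged miRNAs. The intervals held the true ratio for 96.2% of miRNAs. The simulation drew counting error only, so it says nothing about variation between animals. No column of the table was left out.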

Results

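Mature miRNAs were counted by small RNA sequencing in the hippocampus of a Mecp2-/Y male and of a wild type male mouse at postnatal day 30, with 1 library each. Mecp2 is an X-linked gene whose protein binds methylated DNA and is mutated in Rett syndrome, and Mecp2-/Y males carry no functional copy. The wild type library held 9482368 reads and the Mecp2-/Y library 10325080 reads. No replicate was measured in either genotype, so every difference reported lies between 2 libraries and has no replicate check. Intervals are 95% counting intervals.

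Let-7b-5p was the most abundant miRNA of both libraries, with 29.3% of reads in the wild type library (exact binomial interval 29.24 to 29.30%) and 27.0% in the Mecp2-/Y library (26.96 to 27.01%). In the wild type library it was followed by miR-30a-5p with 7.77%, miR-378-3p with 7.14%, let-7c-5p with 6.95% and miR-9-5p with 4.11%. In the Mecp2-/Y library let-7c-5p held 7.23%, miR-30a-5p 6.63%, miR-379-5p 4.50% and miR-9-5p 4.19%. The 5 most abundant miRNAs took 55.2% of the wild type reads and 49.5% of the Mecp2-/Y reads. The 592 measured miRNAs held 99.99% of the reads of each library.

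The comparison of the libraries asked which hippocampal miRNAs differ when MeCP2 is missing. Listed miRNAs of the imprinted Dlk1-Dio3 domain, expressed from the maternal chromosome and abundant in neurons, were mostly higher in the Mecp2-/Y library: 68 of 83 measured members had a ratio above 1, with a median log2 ratio of 0.39. With 9 more arms of hairpins that lie among them, added after the values were seen, 74 of 92 had a ratio above 1. Among the added arms, miR-3071-3p and miR-3071-5p had 2897 and 2411 reads over both libraries. The listed miR-136-5p and miR-136-3p had nearly the same numbers, 2884 and 2305. The same reads may be counted under both names, so the larger count is not separate support. MiRNAs typical of choroid plexus and ependyma were mostly lower: 19 of 23 had a ratio below 1, with a median 1.84-fold lower than in the wild type library. Among the single miRNAs with many reads were miR-129-2-3p, 4.30-fold higher (interval 3.79 to 4.90), miR-335-3p, 3.72-fold higher (3.21 to 4.31), miR-3086-5p, 3.59-fold lower (3.26 to 3.95), and the abundant miR-378-3p, 2.48-fold lower (2.47 to 2.49). The other arms of the miR-129 and miR-335 hairpins did not rise alike: miR-335-5p differed by 1.07-fold (0.989 to 1.16) and miR-129-5p was lower. MiR-134-5p, a Dlk1-Dio3 miRNA that acts on dendritic spines, was nearly level at 1.04-fold lower (1.02 to 1.05), and its direction turned with the scaling.

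Of the 592 measured miRNAs, 52 were at least 2-fold higher in the Mecp2-/Y library, 27 were at least 2-fold lower and 513 were neither. The ratio was above 1 for 315 miRNAs, or 53.2% (exact binomial interval 49.1 to 57.3%). TMM scaling sets the centre of the ratios, so this share cannot show a general rise or fall. The interval treats miRNAs as independent, which arms and clusters that share a transcript are not. The median log2 ratio of all measured miRNAs was 0.03, and scaling by the total count moved it to 0.32, so directions under that scaling are to be read against this shift. Under that scaling 94 miRNAs were higher, 11 were lower and 73.3% had a ratio above 1. The log2 ratios had an SD of 0.73 across miRNAs, 0.97 for the 156 miRNAs under 100 reads and 0.57 for the 238 miRNAs with at least 1000 reads.

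**Figure D1:**
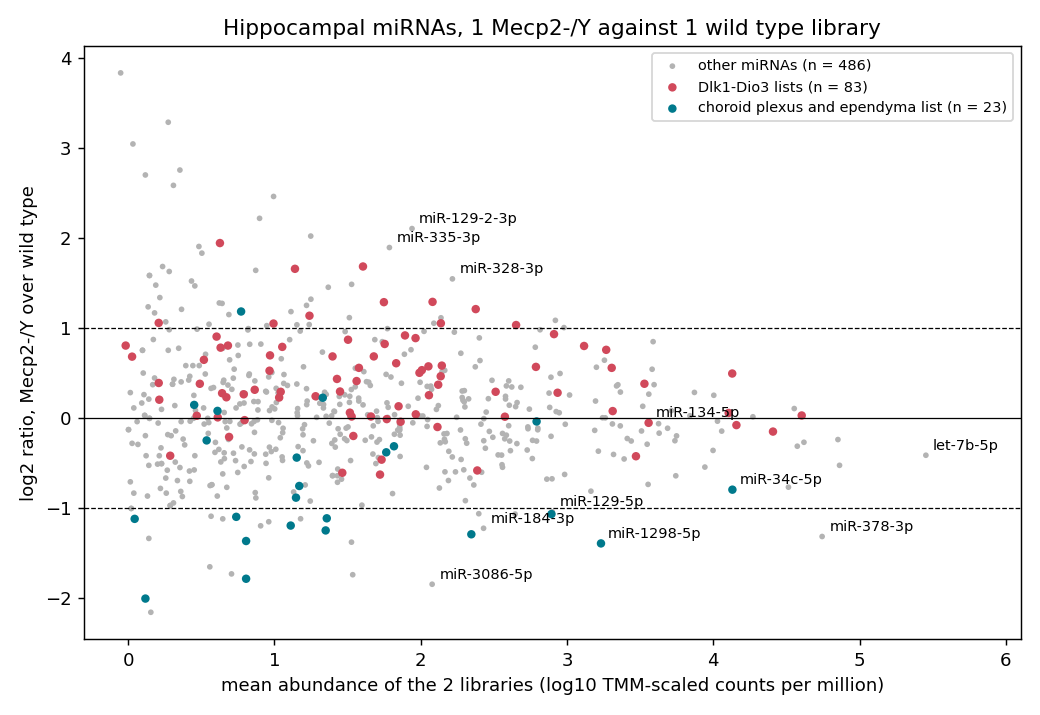
Log2 ratio of the Mecp2-/Y to the wild type library (vertical axis, TMM scaling) against mean abundance on a log scale (horizontal axis), with 1 point per measured miRNA and dashed lines at 2-fold. Of 592 miRNAs, 52 were called higher and 27 lower, and the spread widened toward low abundance.

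The 10 highest-ranked higher miRNAs included several with low counts. MiR-1249-3p rose from 26 to 191 reads, 5.5-fold higher after scaling (interval 3.64 to 8.64), and miR-3085-3p from 60 to 325 reads, 4.06-fold higher (3.07 to 5.44). MiR-328-3p was the most abundant of the 10 with 720 and 2806 reads, 2.92-fold higher (2.69 to 3.17). MiR-335-3p lies within Mest, a paternally expressed imprinted gene, while the other arm of its hairpin, miR-335-5p, differed by 1.07-fold (0.989 to 1.16). MiR-770-5p lies within Meg3, the maternally expressed long noncoding RNA of the Dlk1-Dio3 domain, and was 3.21-fold higher (2.71 to 3.83). MiR-3059-5p was 4.65-fold higher (3.01 to 7.49). MiR-196b-5p, a miRNA of the Hox clusters, went from 3 to 39 reads, miR-1247-5p from 5 to 45 and miR-653-5p from 5 to 40, so their folds of 9.74 (3.10 to 49.3), 6.74 (2.69 to 21.8) and 5.99 (2.37 to 19.5) are known only roughly. These last 3 did not reach the stricter minimum of 100 reads. All 52 higher calls were kept under each of the 3 other scalings, which could hardly lose them. Scaling by the total count adds 0.29 to every log2 ratio, and scaling without the 5 most abundant miRNAs adds 0.09. DESeq2 size factors shift it by only -0.004.

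Among the 10 highest-ranked lower miRNAs were 3 that lie within the serotonin receptor gene Htr2c on the X chromosome. These were miR-1298-5p, 2.62-fold lower (interval 2.56 to 2.68), miR-1298-3p, 2.09-fold lower (2.02 to 2.16), and miR-448-3p, 2.44-fold lower (2.29 to 2.60). MiR-378-3p, which lies within the metabolic coactivator gene Ppargc1b, fell from 677382 to 363937 reads, 2.48-fold lower after scaling. MiR-184-3p, whose gene is imprinted and was tied to MeCP2 by earlier work, was 2.33-fold lower (2.20 to 2.47). MiR-200a-3p, a miRNA of epithelial cells, was 3.44-fold lower (2.28 to 5.31) on 85 and 33 reads. The others were miR-5103 at 3.33-fold lower (2.80 to 3.98), miR-5111-5p at 2.59-fold lower (2.20 to 3.07) and miR-871-3p at 3.31-fold lower (2.09 to 5.39). MiR-871-3p, with 67 and 27 reads, did not reach the stricter minimum of 100 reads. Scaling by the total count kept 7 of these 10 at 2-fold or more and lost miR-1298-3p, miR-184-3p and miR-448-3p, all of which stayed below 1.

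**Figure D2:**
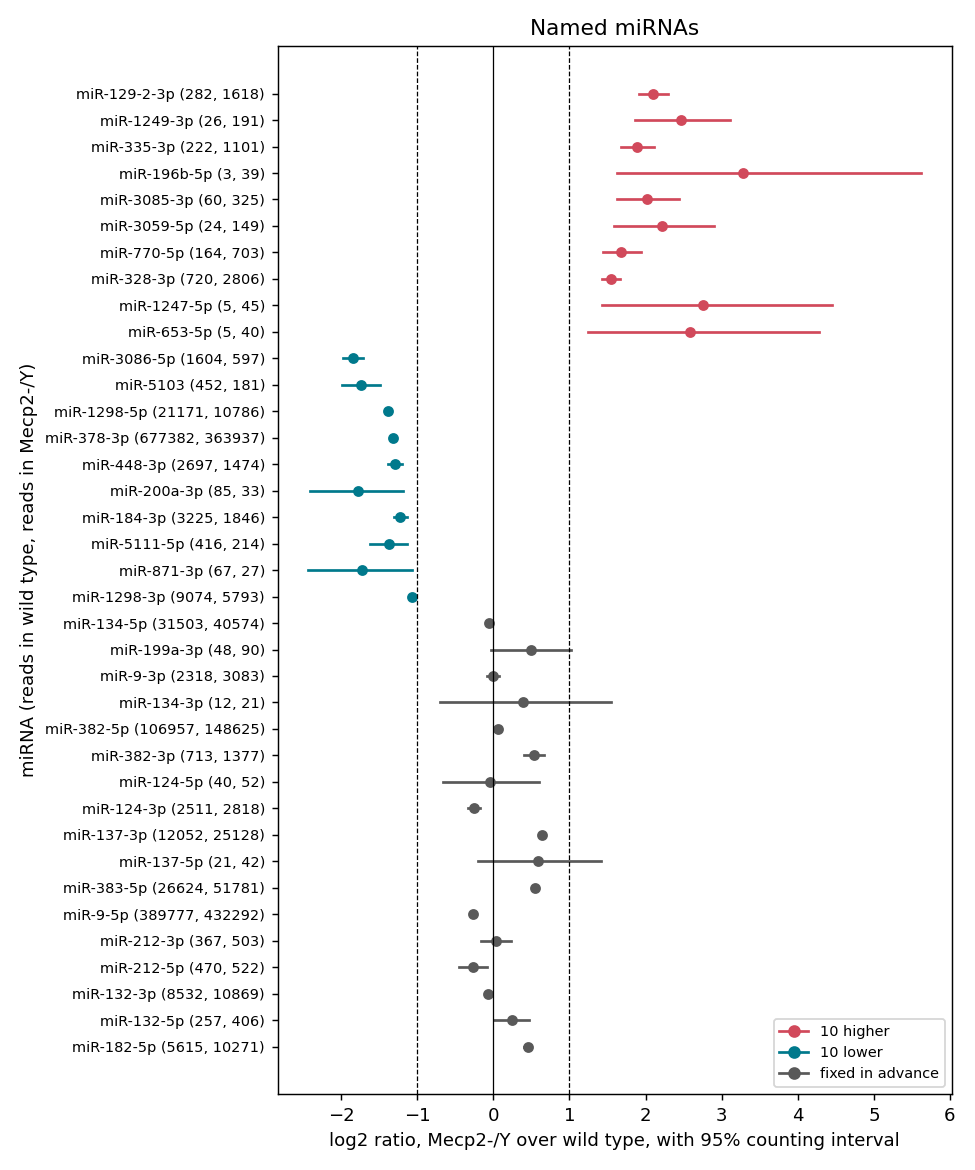
Log2 ratio of the Mecp2-/Y to the wild type library (TMM scaling, horizontal axis) for named miRNAs, each with its 95% counting interval. MiR-129-2-3p lies at 2.10 and miR-3086-5p at -1.84, and the intervals of miR-196b-5p and miR-1247-5p are wide because the wild type library held 3 and 5 reads of them.

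Several miRNAs tied to neurons or to MeCP2 by earlier work were short of 2-fold. MiR-382-5p differed by 1.04-fold (interval 1.03 to 1.05), and miR-134-5p had a log2 ratio of -0.05, or 0.24 under scaling by the total count. MiR-182-5p was 1.37-fold higher (1.33 to 1.42), miR-383-5p 1.46-fold higher (1.44 to 1.48) and miR-137-3p, a regulator of neuronal maturation, 1.56-fold higher (1.53 to 1.60), each short of 2-fold. The less abundant arm miR-382-3p was 1.45-fold higher (1.32 to 1.59), while miR-134-3p with 12 and 21 reads and miR-137-5p with 21 and 42 reads had intervals that held 1. MiR-132 and miR-212, which share a transcript induced by neuronal activity, had log2 ratios of -0.07 for miR-132-3p, 0.24 for miR-132-5p, 0.04 for miR-212-3p and -0.27 for miR-212-5p, with miR-132-3p and miR-212-5p turning above 0 under scaling by the total count. MiR-124-3p, the neuronal miRNA, stood at -0.25 and miR-9-5p at -0.27, and both also turned above 0 under that scaling, as did miR-124-5p at -0.04 and miR-9-3p at -0.01. MiR-199a-3p, with 48 and 90 reads, differed by 1.40-fold with an interval that held 1 (0.979 to 2.04). The list of MeCP2-linked miRNAs had 2 higher and 1 lower call (0 lower under scaling by the total count) and 20 neither, with a median of 0.13 at percentile 87.3. The calls were miR-184-3p, lower, and both arms of miR-7b, higher at log2 ratios of 1.09 for miR-7b-5p and 1.34 for miR-7b-3p (8 and 27 reads), with miR-7b named after its values were seen. The list holds miR-134, miR-182, miR-382 and miR-383, which the study behind these libraries is known for, so it is not independent evidence of a direction. The miR-379 to miR-410 list also holds miR-134 and miR-382, and the list of miR-183, miR-96 and miR-182 holds miR-182. MiR-134 stands in the activity-regulated list and miR-382 in the neuron-enriched list. Those lists may therefore not be independent of that study either, though they were fixed before the data were examined.

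Of the 21 lists, 6 had a median outside the central 95% of random lists of matched abundance. Several of these 6 lists share members, so they are not 6 separate results. The miR-379 to miR-410 cluster had 6 members called higher (15 under scaling by the total count), 0 called lower and 52 neither, and its median log2 ratio of 0.40 lay above all 10000 random lists. Its most abundant members differed little, with miR-379-5p at 0.03 and miR-541-5p at -0.08, the latter turning above 0 under scaling by the total count. With counts summed over arms and copies the cluster's median was 0.21 at percentile 95.2, no longer outside the central 95%. The other Dlk1-Dio3 miRNAs had 4 called higher (7 under scaling by the total count), 0 called lower and 21 neither, with a median of 0.38 at percentile 99.8 (97.1 with at least 100 reads, inside the central 95%), and examples were miR-434-3p at 0.50, miR-434-5p at 0.56, miR-770-3p at 0.38 and miR-127-3p at -0.15 (above 0 under scaling by the total count). The neuron-enriched list had 6 called higher and 1 called lower (12 and 0 under scaling by the total count) and 36 neither, with a median of 0.29 at percentile 99.5 (95.5 with counts summed over arms and copies, inside the central 95%), and 26 of its 43 members stand in another list. Without the members of the Dlk1-Dio3 lists, a choice made after the values were seen, its median was 0.26 at percentile 95, inside the central 95%. MiR-138-5p, an activity-regulated miRNA of that list, was 1.22-fold higher (1.20 to 1.25).

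The choroid plexus and ependyma list had 10 members called lower, 1 called higher and 12 neither (4 called lower under scaling by the total count), and its median of -0.88 lay below all 10000 random lists. These 10 were among the 27 lower calls of the whole table, and the higher call was miR-1264-5p, 2.27-fold higher on 31 and 94 reads, named after its values were seen. MiR-34c-5p, a miRNA of multiciliated cells, was its most abundant member and was 1.73-fold lower (interval 1.72 to 1.75). MiR-204-5p, abundant in choroid plexus, did not move with the rest, at 1.03-fold lower (0.990 to 1.06), and turned above 0 under scaling by the total count, while its other arm miR-204-3p, named after its values were seen, was called lower at a log2 ratio of -1.19 (-0.90 under that scaling). Of the 23 members, 13 stand in another list, and without the miR-200 family and miR-34b and miR-34c, a choice made after the values were seen, the median was -0.31 at percentile 3.41, inside the central 95%. The family of miR-34 and miR-449 had 2 called lower, 0 called higher and 4 neither (0 called lower under scaling by the total count), with a median of -0.77 at percentile 0.145. Of its 6 members, 5 (the arms of miR-34b and miR-34c, and miR-449a-5p) also stand in the choroid plexus and ependyma list, so it is not separate support for that list. The calls were miR-34b-3p, 2.16-fold lower (1.77 to 2.64), and miR-34c-3p, 2.37-fold lower (1.94 to 2.91) and named after its values were seen, while miR-34b-5p was 1.30-fold lower (1.16 to 1.46) and miR-449a-5p 1.17-fold higher (0.961 to 1.43). The miR-30 family had a median of -0.42 at percentile 0.605 with 0 calls among 11 members, which ranged from -0.64 to 0.42, and its most abundant members were miR-30a-5p at -0.52, miR-30a-3p at -0.54, miR-30e-5p at 0.02 and miR-30d-5p at 0.11. Summed over arms and copies, that family's median was -0.13 at percentile 35.5.

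**Figure D3:**
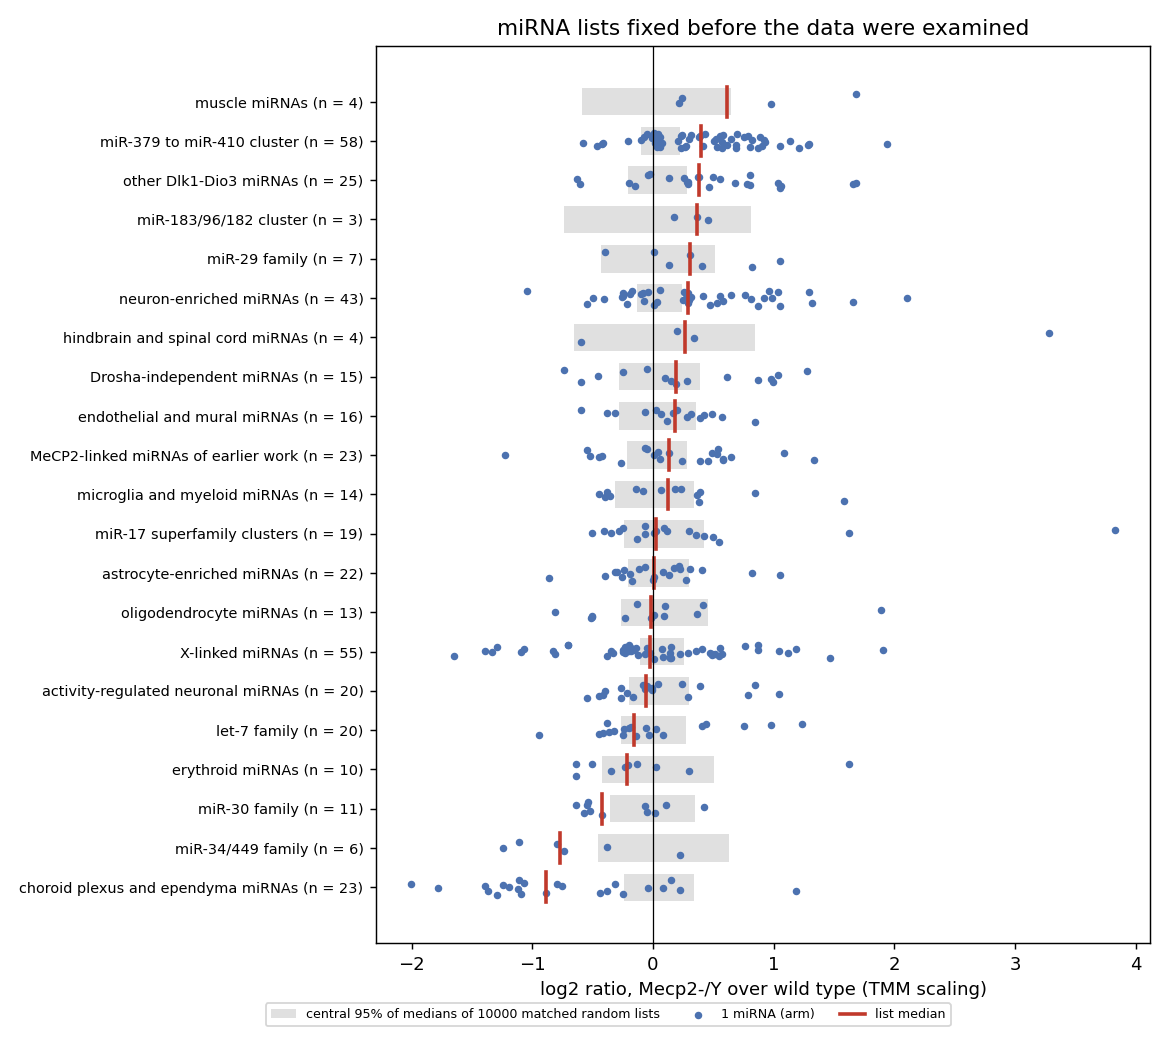
Log2 ratio of the Mecp2-/Y to the wild type library (TMM scaling, horizontal axis) for the measured members of each list, with the list median as a bar and the central 95% of the medians of 10000 random lists of matched abundance in grey. The choroid plexus and ependyma median at -0.88 lies farthest below its grey range, and the miR-379 to miR-410 median at 0.40 lies above its own.

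Lists for glia, vessels and blood lay inside the central 95% of random lists. Oligodendrocyte miRNAs had a median of -0.02 at percentile 31.5 with miR-335-3p as the 1 higher call among 13, and miR-219-2-3p and miR-338-5p, of hairpins tied to oligodendrocyte maturation, were 1.75-fold (interval 1.71 to 1.80) and 1.43-fold (1.36 to 1.5) lower. Other arms of the miR-219 and miR-338 hairpins, chosen after their values were seen, were mixed. MiR-219-5p had a log2 ratio of 0.41 (-0.08 to 0.92), while that of miR-219-1-3p lay 0.91 below that of miR-219-5p. MiR-338-3p had -0.13 (-0.29 to 0.02) and turned above 0 under scaling by the total count. Astrocyte-enriched miRNAs had a median of 0.005 at percentile 43.3 with 1 higher call among 22, with miR-143-3p at -0.31 and miR-21-5p at -0.11, the latter turning above 0 under scaling by the total count. Microglia and myeloid miRNAs had a median of 0.12 at percentile 75.4, with 1 higher call among 14 and miR-146a-5p, an inflammatory miRNA, 1.36-fold lower (1.31 to 1.42). Endothelial and mural miRNAs had a median of 0.18 at percentile 82.7 with 0 calls among 16, and the endothelial miR-126-3p was 1.80-fold higher (1.77 to 1.83) while miR-126-5p differed by 1.05-fold (0.994 to 1.11). Erythroid miRNAs had a median of -0.22 at percentile 11.9 with 1 higher call among 10, and miR-451 and miR-144-5p stood at -0.21 and -0.23. Under scaling by the total count the higher calls were 2 for astrocytes, 2 for microglia and myeloid cells and 1 for endothelial and mural cells. The medians of the oligodendrocyte and erythroid lists and the values of miR-451 and miR-144-5p turned above 0 under scaling by the total count.

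The remaining lists also lay inside that range. The cluster of miR-183, miR-96 and miR-182 had a median of 0.37 at percentile 87.1 and 0 calls among 3 members. Activity-regulated neuronal miRNAs had a median of -0.06 and a mean of 0.04, at percentile 23.1, with 1 higher call among 20. The let-7 family had a median of -0.16 at percentile 12.7 and 0 calls among 20, with let-7b-5p 1.33-fold lower and let-7c-5p 1.18-fold lower. The medians of these last 2 lists and let-7c-5p turned above 0 under scaling by the total count. The miR-17 family clusters had a median of 0.02 at percentile 40.7 with 2 higher calls among 19. With at least 100 reads their median was -0.06 at percentile 13.8. The miR-29 family had a median of 0.31 at percentile 88.8 with miR-29b-3p called higher at 2.08-fold (interval 1.90 to 2.27). All 4 muscle miRNAs were above 1, with a median of 0.61 at percentile 96.6 (97.8 with counts summed over arms and copies, outside the central 95%), miR-206-3p 1.97-fold higher (1.90 to 2.05) and miR-499-5p called higher on 7 and 30 reads. Over the 3 muscle miRNAs with at least 100 reads the median was 0.24 at percentile 81.2. Of these, miR-1a-3p (2981 wild type and 4708 Mecp2-/Y reads) and miR-1b-5p (3016 and 4667) had nearly equal counts. The same reads may be counted under both names, so the 4 muscle miRNAs may not be 4 separate ones. Hindbrain and spinal cord miRNAs had a median of 0.27 at percentile 73.2 with miR-196b-5p as the 1 higher call among 4 members, or -0.20 over the 2 members with at least 100 reads, with miR-10b-5p 1.15-fold higher (1.08 to 1.22) and miR-10a-5p 1.51-fold lower (1.40 to 1.63). Drosha-independent miRNAs had a median of 0.19 at percentile 78.8 with 2 higher calls among 15, and miR-320-3p was 1.51-fold lower (1.41 to 1.62). X-linked miRNAs had 5 higher and 6 lower calls among 55 (8 and 2 under scaling by the total count), with a median of -0.02 and a mean of 0.01 at percentile 17.9, and the median turned above 0 under scaling by the total count. That scaling also gave 3 higher calls for the activity-regulated, 2 for the let-7, 2 for the miR-29, 2 for the muscle and 4 for the Drosha-independent list.

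The 5p and 3p arms of a hairpin come from 1 precursor and gave a look within the libraries at how far ratios repeated. Across 172 hairpins with both arms measured, without those that share an arm between genomic copies (such as miR-129), the log2 ratios of the arms correlated with a Spearman coefficient of 0.385 and a Pearson coefficient of 0.290, and 117 hairpins had both arms on the same side of 1. With at least 100 reads in each arm these were 0.452 and 0.459 across 103 hairpins, of which 75 had both arms on the same side. The SD of the difference between arms was 0.84 for all 172 hairpins and 0.59 for these 103. These correlations run across miRNAs, which are not independent replicates. The counting interval of an abundant miRNA was far narrower than this difference between arms.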

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

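No paired analysis was possible because each genotype had 1 library and no test was run, and leaving out a replicate was not possible for the same reason. The alternatives were planned except the ones that left out members of lists, which were chosen after seeing the data. Against 52 higher and 27 lower calls of 592 miRNAs, scaling by the total count gave 94 and 11, a 1.5-fold threshold 96 and 67, and a 3-fold threshold 19 and 7. Counts summed over arms and copies gave 24 and 13 of 391, and a minimum of 100 reads gave 31 and 20 of 436. Without the Dlk1-Dio3 and choroid plexus and ependyma lists 41 higher and 17 lower calls of 486 miRNAs were left. The share of miRNAs with a ratio above 1, 53.2%, was 73.3% under scaling by the total count and 60.1% under scaling without the 5 most abundant miRNAs. Under scaling by the total count, list medians were 0.70 for the miR-379 to miR-410 cluster, 0.66 for the cluster of miR-183, miR-96 and miR-182, 0.23 for activity-regulated, 0.58 for neuron-enriched, 0.28 for oligodendrocyte, 0.30 for astrocyte-enriched, 0.42 for microglia and myeloid, 0.48 for endothelial and mural, 0.13 for let-7 and 0.27 for X-linked miRNAs. These shifts follow from that scaling, which adds 0.29 to every log2 ratio. The median of the miR-379 to miR-410 cluster was 0.21 with counts summed over arms and copies. A sum weights each hairpin toward its more abundant arm. For its most abundant members, miR-379-5p, miR-541-5p, miR-382-5p and miR-134-5p, the log2 ratios were 0.03, -0.08, 0.06 and -0.05. Their less abundant 3p arms stood at 0.32, 0.30, 0.53 and 0.39. Other hairpins went the other way, such as miR-410 and miR-300, whose more abundant 3p arms stood at 1.21 and 0.93 against 0.70 and 0.65. How much of the lower median this explains was not tested. The median of the cluster of miR-183, miR-96 and miR-182 was 0.46 when scaled without the 5 most abundant miRNAs, which adds 0.09. Over all results and alternatives, 282 values stayed within their limits, 161 moved beyond them and 0 called values changed direction. For a single miRNA the limits were its counting interval, so an abundant miRNA moved beyond them under a small shift. Of the 96 named miRNAs, 23 changed direction with the scaling, and 0 of these were called, with those nearest 0 turning also under scaling without the 5 most abundant miRNAs. A called miRNA could not change direction with the scaling, since a call needs at least 2-fold, or 1 in log2, and the largest shift was 0.29. Depth limits the rarer miRNAs: the SD of log2 ratios was 0.97 under 100 reads against 0.57 at 1000 reads or more.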

Other observations

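The GC tests were planned before their results were seen, and all other tests and all groups in this part were chosen after the values were seen. A cluster of X-linked hairpins within the chloride channel gene Clcn5, which holds miR-188, miR-362, miR-500, miR-501 and miR-532, had a median log2 ratio of 0.69 over 8 measured arms, at percentile 98.7 of random lists. Of these arms, 3 were called higher, miR-188-5p at 1.04, miR-501-5p at 1.91 (66 reads over both libraries) and miR-532-3p at 1.12 (685 reads). The more abundant arms of the last 2 hairpins were miR-501-3p at 0.52 (2867 reads) and miR-532-5p at -0.23 (7420 reads). MiR-532-5p turned above 0 under scaling by the total count. Both arms of miR-488, which lies within the neuronal gene Astn1, were called higher, at 2.01-fold (interval 1.95 to 2.07) for miR-488-3p and 2.80-fold (2.34 to 3.37) for miR-488-5p. MiR-7b-5p, a miRNA of neurons and neuroendocrine cells and a member of the list of MeCP2-linked miRNAs, was 2.12-fold higher (2.05 to 2.20) on 4570 and 12946 reads.

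Other groups were lower in the Mecp2-/Y library. The cluster of miR-99b, let-7e and miR-125a had a median of -0.61 over 6 arms at percentile 0.62, with the abundant miR-99b-5p 1.70-fold lower (1.69 to 1.71) and miR-125a-5p 1.20-fold higher (1.19 to 1.22). MiR-375-3p, a miRNA of endocrine cells, was 2.08-fold lower (1.97 to 2.21), or -0.77 in log2 and short of 2-fold under scaling by the total count. The arms of the 4 hairpins within Htr2c did not move as 1 group: of 8 arms, 5 were below 1 and 3 above, among them miR-1264-5p, called higher at 2.27-fold (1.5 to 3.53) on 31 and 94 reads. These groups were picked from 26 clusters of neighbouring hairpins and from the table of calls.

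The choroid plexus and ependyma miRNAs were mostly lower in the Mecp2-/Y library, with 19 of 23 at a ratio below 1. Of these 23, 10 were called lower, or 4 under scaling by the total count. Hairpin GC content does not account for the lower median, since removing the trend of the ratio on GC left it at -0.85, from -0.88. Without the miR-200 family and miR-34b and miR-34c, the median was -0.31 at percentile 3.4. That percentile is not below the limit of 2.5 used here, and this subset was chosen after the values were seen. A candidate explanation is a smaller amount of choroid plexus or ependyma in the dissected Mecp2-/Y sample. By the more abundant arm, 11 of 13 hairpins were lower, with a median of -0.79, and 6 were lower by more than the SD between arms of 0.84, but miR-1264-5p was called higher at 1.18, miR-449a-5p stood at 0.23, and the interval of miR-204-5p at -0.04 held 1. The most abundant member, miR-34c-5p, was 1.73-fold lower after scaling, 13 of the 23 stand in another list, and how many the hippocampus itself expresses was not measured here. With 1 library per genotype, dissection and genotype cannot be told apart, and an effect of genotype stays open and untested.

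The listed Dlk1-Dio3 miRNAs were mostly higher in the Mecp2-/Y library, with 68 of 83 above 1 but only 10 called higher. Here too removing the GC trend left their median in place, at 0.41 from 0.39. Their standing is less firm under other choices: summed over arms and copies, the miR-379 to miR-410 cluster had a median of 0.21 at percentile 95.2, and with at least 100 reads the other Dlk1-Dio3 list lay at percentile 97.1, both inside the central 95%. A larger share of neurons in the sample may raise them. The 26 neuron-enriched miRNAs outside the domain had a median of 0.26, with 14 above 1 and 12 below and an SD of 0.69. A larger share of neurons was to be rejected only by a median more than this SD below that of the domain. So wide a spread made that hard to reach, and the comparison could not decide. An effect of genotype on this imprinted domain stays open and untested, as does a difference between the 2 animals.

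The arms of miR-129 went opposite ways, with the shared miR-129-5p 2.06-fold lower (interval 1.99 to 2.12, short of 2-fold under scaling by the total count) and miR-129-1-3p and miR-129-2-3p higher by log2 ratios of 1.32 (0.97 to 1.68) and 2.10 (1.92 to 2.29). The 3p minus 5p differences were 2.36 and 3.14, while the median over 172 other hairpins was -0.029 with an SD of 0.84, which argues against a general change in the balance of arms. A shared arm beside copy-specific arms does not usually behave so, since 1 of 21 other miRNAs of this kind differed by at least 2, on 1 and 19 reads of miR-19b-1-5p. Among the 172 other hairpins, 1 reached the smaller miR-129 difference, miR-1198 at 2.98, on 29 reads of its 3p arm. In the opposite direction miR-1247 stood at -3.07 and miR-210 at -3.06, on 50 and 24 reads of their 5p arms. A candidate explanation is a change in arm choice or arm stability at miR-129, a hypothesis found in these same data, and no test here separates it from genotype or from sampling of a single animal.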
